A study of Rattus with 6 samples.

How the data were processed

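RNA sequencing of 6 libraries of the rat pituitary line RC-4B/C was analysed, 3 labelled ASA and 3 labelled DMSO. Replicate numbers name the libraries in their deposited order. The labels state no pairing between the groups and none was used, though a pairing that they leave out cannot be ruled out. Per the labels' protocols, total RNA was extracted with a column kit and polyadenylated RNA was made into directional libraries. The submitters' processing notes name Trim Galore 0.4.1, cutadapt 1.14, TopHat2 2.1.0, Bowtie2 and edgeR 3.26.8 and the rat genome build Rnor_6.0, without role or order. The counting tool, its use of strand and the annotation release are not given in the sources used here. The deposited values are log2 RPKM, 1 row per exon and 1 column per library, with the exon's position and length. The table has 118147 exons of 12801 genes and no fold change or p-value columns, so a planned comparison with the authors' calls was not made. All 6 value columns were mapped to samples by the code in the sample titles.

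What the values hold was checked on the table. Undoing the log and multiplying by exon length gave reads per 1000000 that summed to 1000344 in every library, so no scaling factor between libraries was visible. The lowest values were a constant of 0.00292 reads per 1000000, equal to 0.25 read at the mean depth of 85761055, plus multiples of what 1 read is worth. After that constant was removed, 95.7% to 96.8% of values in each library were whole reads within 0.02 read, and most of the rest were multiples of 0.5 read (2.9% to 4.0% of values), so some reads had been divided between features. Depth in the listed exons ranged from 66492445 to 94486062 reads. In every exon row at least 4 of the 6 libraries had over 10 reads, so an exon seen in only 1 of the groups cannot be in the table. Genes that share reads with near-identical copies are uncertain, and reads of overlapping antisense genes cannot be ruled out where the use of strand is not stated.

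Gene values were computed as the sum of reads over a gene's listed exons per kilobase of those exons per 1000000 reads, on the linear scale after removing the constant. A symbol on more than 1 gene identifier (29 symbols) was represented in gene lists by the one with the highest mean. The main test, fixed before the data were examined, was limma 3.58.1 (lmFit, eBayes with a mean-variance trend, two-sided) on log2(RPKM + 0.1), ASA against DMSO without covariates. It covered the 12502 genes with a mean RPKM of at least 0.5, with 299 genes under that filter, at a Benjamini-Hochberg adjusted p under 0.05. A fold change is taken from the difference between group means of log2(RPKM + 0.1), not from the ratio of mean RPKM. It can lie above or below that ratio where replicates spread widely, and the added 0.1 understates the change of low genes. Count models were planned only if whole-number counts were deposited. They were not run, since the deposited values are log2 RPKM. The 41 gene lists, with 885 symbols of which 681 were in the table, were also fixed in advance. The 38 with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The rule for named genes, fixed in advance, took the 12 highest and 12 lowest log2 fold changes among called genes with a mean RPKM of at least 1, no overlap between the groups and a gene symbol that is not a placeholder. It also took a set of genes whatever their result (Pttg1, Ptgs1, Ptgs2, Tet1, Tet2, Tet3, Dnmt1, Cdkn1a, Ccnd1, Mki67 and the 7 pituitary hormones) and up to 4 members of each list described, by smallest p. Some genes that the rule takes are not reported here. Genes outside this rule describe the identity of the cells or complete a count of 5 or fewer, and the latter (Hk2, Acss2, Smad6, Hexa, Map1lc3a, Vamp2, Plin2 and Nfe2l2) were chosen after their values were seen.

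The fit was tested on simulated data with 200 changed genes. Each gene had its fitted spread, the same in every library and independent of other genes. In the real data ASA replicate 2 stood apart and genes varied together, so the simulated rates may not hold there. The real test also called 1400 genes. Recovery at a given adjusted p depends on the share of changed genes, so the simulated rates can understate it. With all 6 libraries (12483 simulated genes) the fit recovered 75.8% of genes changed 4-fold, 10.4% of those changed 2-fold and 0% of those changed 1.5-fold. Of its 59 calls 2 were unchanged genes. Without ASA replicate 2 (12486 genes) it recovered 95.5%, 43.3% and 3%, with 7 unchanged genes among 101 calls. The alternatives tried were other pseudocounts, filters, scalings and variance models, each library left out, and a minimum fold change. Those added after seeing the data were voom on the recovered reads, library quality weights, the median exon as the gene's value, leaving out both libraries numbered 2, and totals without mitochondrial and Prl reads. Coverage was checked from the scatter of exons within a gene against the DMSO libraries. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.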

Results

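Polyadenylated RNA of RC-4B/C cells, a rat pituitary adenoma cell line, was sequenced after treatment with aspirin (acetylsalicylic acid, ASA), an inhibitor of the cyclooxygenases, or with the solvent dimethyl sulfoxide (DMSO). There were 3 ASA and 3 DMSO libraries. The only comparison the labels define is ASA against DMSO, which asks how aspirin alters the transcriptome of these cells. The series design also names the line GH3, which was not analysed here, and the labels used here give no dose or duration. The labels do not say whether the 3 libraries of a group came from separate cultures, so every p-value measures the spread between these libraries only. The table held 118147 exons of 12801 genes, and values are given per gene as reads per kilobase of listed exon per 1000000 reads (RPKM). The reads in the listed exons, recovered from the table, numbered 92073423, 66492445 and 87360310 in ASA replicates 1, 2 and 3. They numbered 94486062, 82189699 and 91964390 in DMSO replicates 1, 2 and 3. No pair of replicates agreed within sampling noise, with a chi-square per degree of freedom between replicates of a group of 119.5 to 1089.5, so all 6 were kept as separate libraries.

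The libraries carried the transcripts of prolactin-secreting pituitary cells. Prl, which encodes prolactin, had an RPKM of 14037, 62101 and 26174 in ASA replicates 1, 2 and 3, and of 22006, 62170 and 41835 in DMSO replicates 1, 2 and 3. Pou1f1, the transcription factor of the lactotroph, somatotroph and thyrotroph lineages, lay between 584 and 804 in all 6 libraries. The granule protein genes Chgb and Scg2 had 3493 and 2861 in ASA replicate 1. Pomc, the precursor of corticotropin, had at most 2.62. Of the 7 pituitary hormone genes fixed in advance, only Prl, Pomc and Cga had rows in the table. ASA replicate 2 stood apart. Its exons scattered within genes by 0.408 on the log2 scale at equal depth, against 0.081 to 0.098 in the other 5 libraries. It had 497 exons with 0 reads against 4 to 13 elsewhere, and mitochondrial transcripts took 5.44% of its reads against 2.65% to 3.22%. That share was not a general rise. The median of the mitochondrially encoded genes in it was -0.708 (log2) relative to the DMSO mean, against -0.166 to 0.143 in the other 5 libraries. The first principal component, with 62.1% of the variance, placed ASA replicate 2 at 95.5, the other ASA libraries at 2.2 and 30.5 and the DMSO libraries between -51.4 and -30.6. The second, with 23.1%, set it apart from the other ASA libraries. ASA replicates 1 and 3 lay at 43.4 and 42.7, the DMSO libraries between -18.4 and -14.5 and ASA replicate 2 at -36.9.

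**Figure D1:**
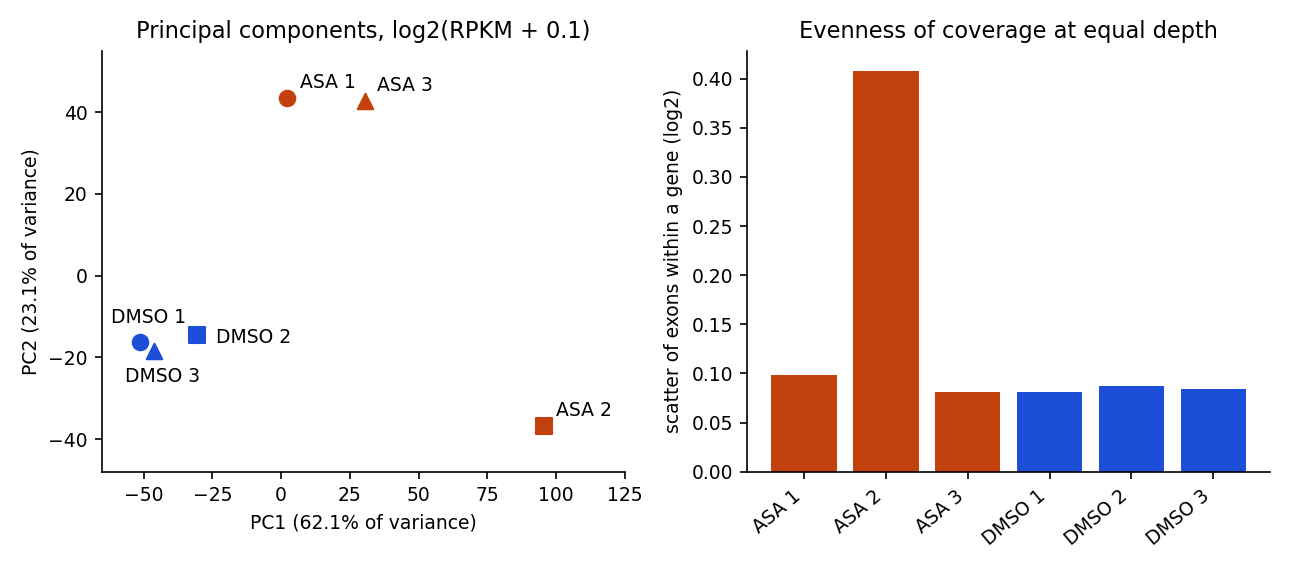
Left: the 6 libraries on the first and second principal components of log2(RPKM + 0.1) over 12502 genes, ASA in orange and DMSO in blue. Right: the scatter of exons within genes (log2 units) of each library at equal depth, which is 0.408 in ASA replicate 2 and at most 0.098 in the others.

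Many genes differed between aspirin-treated and DMSO-treated cells. Among the genes that rose, Cd68, a lysosomal membrane glycoprotein best known from macrophages, went from 2.48 ± 0.55 to 103 ± 95.1 RPKM (SD, n = 3), 29.6-fold. The leukocyte integrin gene Itgax went from 1.45 ± 0.589 to 27.1 ± 5.84, 18.1-fold. Nrip2 rose 19.6-fold, Ifitm10 15.5-fold, Ipcef1 14.6-fold, Bin2 12.5-fold, Ripor3 10.8-fold, Rhov 10.7-fold, the transporter gene Slc16a14 10.4-fold and the lysosomal channel gene Mcoln3 8.91-fold. The stress-induced genes Trib3 and Atf3 rose 13.2-fold and 10.6-fold. Among those that fell, the neuropeptide galanin, Gal, dropped from 142 ± 137 to 4.24 ± 3.45 RPKM, 28.6-fold. The immediate early gene Arc dropped from 102 ± 6.55 to 13.4 ± 16, 16-fold by the log2 means, with 31.5, 0.949 and 7.76 in ASA replicates 1, 2 and 3. Lrrn4 was 18.8-fold lower, Bhlhe23 16.4-fold, Rd3 14-fold, the replication factor gene Pclaf 12.4-fold, Lor 12.3-fold, St18 11.5-fold, and the receptor genes Prokr2 and Gpr139 11.3-fold and 10.2-fold. The alpha-globin genes Hba-a2 and Hba-a3 were 27-fold and 17.8-fold lower. They are near-identical copies whose reads can be assigned to either, so their separate values are uncertain.

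In the limma test (log2 of RPKM + 0.1, Benjamini-Hochberg adjusted p under 0.05), 1400 of 12502 genes changed, 776 higher and 624 lower with ASA. The adjusted p of these 24 genes lay between 0.00906 (Nrip2, Itgax and Ipcef1) and 0.0492 (Arc), and the standard error of the log2 fold change between 0.35 (Itgax) and 1.04 (Arc). Cd68 spans 56268888 to 56270557 of chromosome 10 (ENSRNOG00000037563), Itgax 199556557 to 199576003 of chromosome 1 (ENSRNOG00000036703) and Gal 218653242 to 218657579 of chromosome 1 (ENSRNOG00000015156), from the first to the last listed exon, in Rnor_6.0 coordinates. The number past the threshold did not hold when a library was left out, with 2617 without ASA replicate 2, 632 without DMSO replicate 2, 91 without DMSO replicate 1, and 0 without ASA replicate 3 or without DMSO replicate 3. In the limma fits with no call the smallest adjusted p was 0.0803 and 0.079, and 2926 and 2345 genes had an unadjusted p under 0.05. Of 128 called genes that are named or that the naming rule could take, 12 lost their call without ASA replicate 1, 2 without ASA replicate 2, 106 without DMSO replicate 1 and 63 without DMSO replicate 2. Some folds moved by over 1.5 times without a single library. Without ASA replicate 1, Cd68 was 47.6-fold higher, Bin2 23.5-fold, Ripor3 22.4-fold and Rhov 16.7-fold, while Arc was 35.6-fold lower and Lrrn4 28.5-fold. Without ASA replicate 2, Cd68 was 17.7-fold and Rhov 6.99-fold higher, and Hba-a2 was 44.5-fold lower, Gal 44-fold, Lrrn4 9.96-fold, Gpr139 6.64-fold and Arc 6.48-fold. Ripor3, 6.76-fold higher, lost its call there (adjusted p = 0.0512, and 0.0112 to 0.16 over the 6 fits that each left out a library). Without ASA replicate 3, Atf3 was 6.93-fold higher and Hba-a2 13.7-fold lower. Gal was 48.6-fold lower without DMSO replicate 1. Without DMSO replicate 2, Trib3 was 22.6-fold higher, and Pclaf was 20.3-fold lower, Gal 16.6-fold, Hba-a3 11.8-fold and Lor 8.09-fold.

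**Figure D2:**
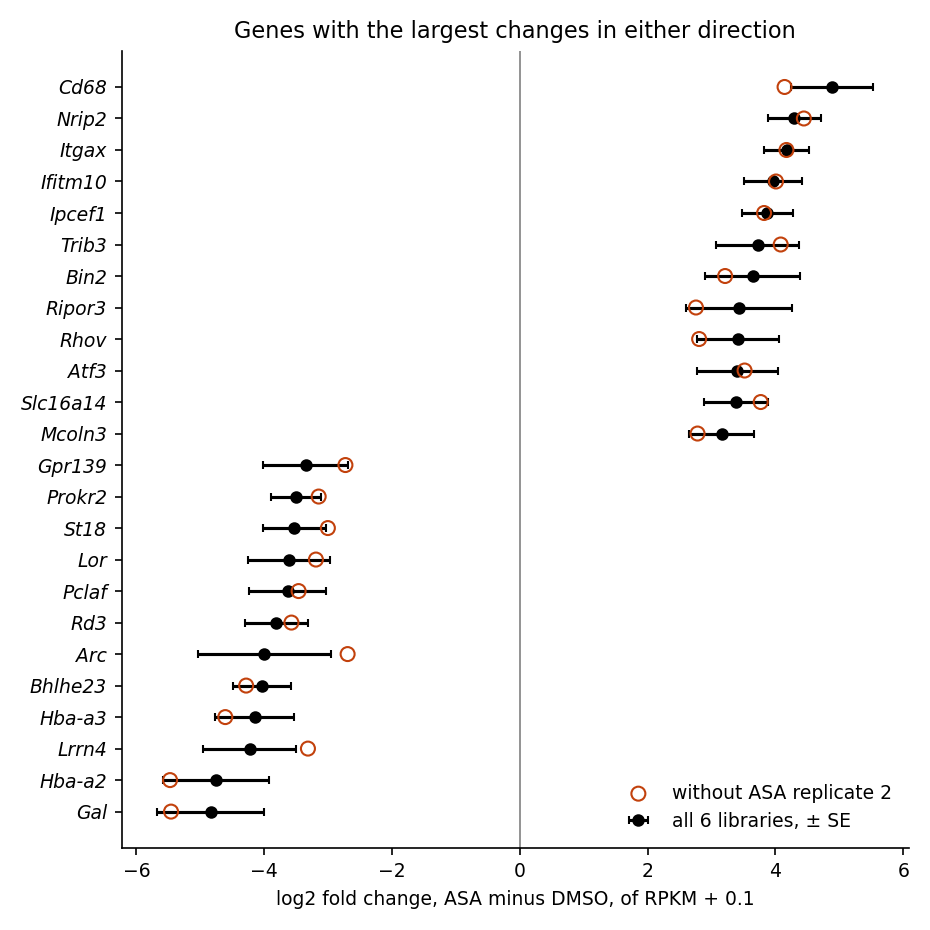
The log2 fold change of ASA against DMSO, computed on RPKM + 0.1, of the 12 genes with the highest and the 12 with the lowest value by the rule fixed in advance. Black points and bars give the fit and its standard error over 6 libraries and open circles the fit without ASA replicate 2, where Arc moves from 16-fold to 6.48-fold lower.

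Many genes of the G2/M and G1/S phases of the cell division cycle were lower with ASA. Pttg1, the securin first found in pituitary tumours, averaged 22.9 ± 5.03 RPKM in ASA and 127 ± 55.2 in DMSO libraries (SD, n = 3), 5.16-fold lower (log2 fold change -2.37 ± 0.38 SE, adjusted p = 0.0173). The proliferation marker Mki67 was 6.62-fold lower (5.67 ± 2.77 against 38.9 ± 20.3, adjusted p = 0.0301), the mitotic cyclin Ccnb1 7.3-fold, the kinesin Cenpe 8.14-fold and the checkpoint kinase Bub1b 5.09-fold. All 31 tested members of the G2/M and mitosis list had a negative log2 fold change, with a median of -2.24. Of these, 24 fell over all genes and 30 adjusted over the list alone. Of the 32 tested members of the G1/S and DNA replication list, 12 fell over all genes and 22 adjusted over the list alone. Among them were the helicase subunits Mcm6 (5.22-fold) and Mcm7 (4.14-fold) and Gins2 (4.36-fold). Cdkn1a, the inhibitor of cyclin-dependent kinases known as p21, rose 2.44-fold (182 ± 60.9 against 72.6 ± 17.2, adjusted p = 0.0402). It was the only one of the 8 tested kinase inhibitors and RB family members past the threshold, over all genes and adjusted over the list alone. Its call was lost without ASA replicate 3 or any single DMSO library, and without both libraries numbered 2 (adjusted p between 0.0162 and 0.161 over the 6 fits that each left out a library). Cdkn1b, Cdkn2c and Cdkn2a had log2 fold changes of -0.44, -0.94 and 0.21 (adjusted p = 0.123, 0.134 and 0.413). Ccnd1, which encodes cyclin D1, averaged 500 ± 126 against 290 ± 26.4, a log2 fold change of 0.76 ± 0.22 that missed the threshold (adjusted p = 0.063). It passed without ASA replicate 2 (adjusted p between 0.0367 and 0.254 over the 6 fits that each left out a library).

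DMSO replicate 2 lay between the groups for these genes. Its Pttg1 value was 63.3, against 161 and 156 in DMSO replicates 1 and 3 and 19.5 to 28.7 in the ASA libraries. The median of the G2/M list in it was -1.09 relative to the DMSO mean, with 0.77 and 0.34 in the other DMSO libraries and -2.13 to -2.18 in the ASA libraries. Pttg1 spans 29020106 to 29025479 of chromosome 10 and Mki67 207994172 to 208020208 of chromosome 1 (Rnor_6.0). Both lists were lower than other genes in camera with a preset correlation (adjusted p = 1.79e-14 for G2/M and 3.38e-10 for G1/S). Neither passed with an estimated correlation (adjusted p = 0.587 and 0.618). In splits of the libraries that mixed the groups the preset test called up to 12 lists, against 13 in the real split. Such splits still hold part of any difference between ASA and DMSO, so they are not a background without an effect. Preset calls, here and below, do not by themselves show an effect of ASA. The number of G2/M genes past the threshold was 24 without ASA replicate 2, 28 without DMSO replicate 2, and 0 without ASA replicate 3, DMSO replicate 1 or DMSO replicate 3. For G1/S these counts were 10, 20 and 0. Pttg1 was 4.4-fold to 7.01-fold lower over the 6 fits that each left out a library.

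**Figure D3:**
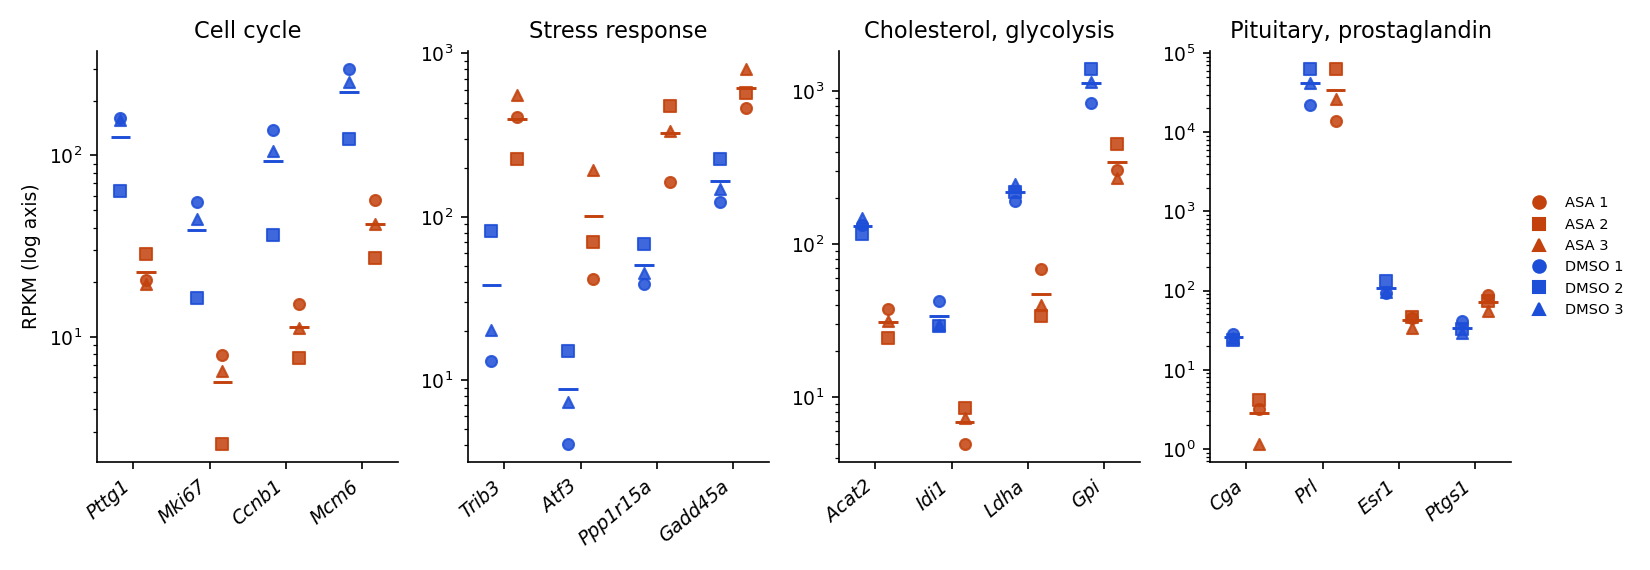
RPKM of 16 genes in each library on a log axis, DMSO in blue and ASA in orange, with symbols for replicates 1 to 3 and a bar at each group mean. The ASA and DMSO values do not overlap for any gene shown except Prl, and DMSO replicate 2 is the lowest DMSO library for Pttg1, at 63.3, and for Mki67, at 16.4.

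Some genes of the integrated stress response and some targets of p53 rose, and neither list passed with an estimated correlation (adjusted p = 0.798 and 0.587). In the list of the amino acid response and integrated stress response, 10 of 29 tested members rose and none fell (12 higher adjusted over the list alone). Ppp1r15a, a regulatory subunit of the phosphatase of eIF2 alpha, was 6.01-fold higher (325 ± 157 against 50.6 ± 15.4 RPKM, adjusted p = 0.0159), and Cebpb 3.05-fold, beside Trib3 and Atf3. Of 23 tested p53 targets 7 rose and none fell (7 higher and 1 lower adjusted over the list alone). Gadd45a rose 3.72-fold, the kinase gene Plk3 3.37-fold, the nuclease gene Aen 2.29-fold and Phlda3 2.14-fold. Of the Gadd45a and Plk3 values 33.3% and 26.7% were not whole reads. The unfolded protein response of the endoplasmic reticulum was split, with 4 of 23 tested members past the threshold (4 higher and 3 lower adjusted over the list alone). The sensor Atf6 and the chaperone Hspa5 rose 2.64-fold and 2.78-fold, while Pdia4 and Creld2 fell 2.26-fold and 1.91-fold. In this list 3 rose and 3 fell without ASA replicate 1, 2 and 3 without ASA replicate 2, 1 and 0 without DMSO replicate 2, and none without DMSO replicate 1. Among 22 tested apoptosis regulators 1 rose and 2 fell (2 and 2 adjusted over the list alone). The counts were 0 and 2 without ASA replicate 1, 3 and 3 without ASA replicate 2, 0 and 1 without DMSO replicate 2, and 0 without any 1 of the other 3 libraries. The survival gene Bcl2l1 was 2.33-fold higher, and kept its call only without ASA replicate 2 (adjusted p between 0.006 and 0.162 over the 6 fits that each left out a library). Birc5, a mitotic gene that also blocks apoptosis, was 3.21-fold lower. Bcl2 averaged 25.7 ± 11.3 against 9 ± 1.86, with an adjusted p of 0.0616, and passed without ASA replicate 2 (adjusted p between 0.00816 and 0.192 over the 6 fits that each left out a library).

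The median of the integrated stress response list was 0.52 above the DMSO mean in DMSO replicate 2, against 0.21 in ASA replicate 2 and 0.73 and 0.94 in ASA replicates 1 and 3. Camera with a preset correlation, but not with an estimated one, placed the integrated stress response (preset adjusted p = 0.000173) and p53 lists (preset adjusted p = 0.00207) above other genes. The unfolded protein response and apoptosis lists did not pass either way (preset adjusted p = 0.811 and 0.345). In the integrated stress response list 12 genes rose without ASA replicate 2, 8 without DMSO replicate 2, and none without ASA replicate 3, DMSO replicate 1 or DMSO replicate 3. Of the p53 targets 9, 2 and none rose, and 2 fell without ASA replicate 2. Hspa5 lost its call without ASA replicate 2 (adjusted p = 0.0579, and 0.016 to 0.191 over the 6 fits that each left out a library).

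Some genes of lipid and energy metabolism fell. Of 26 tested genes of cholesterol biosynthesis, 10 fell and none rose (13 lower adjusted over the list alone). Acat2 was 4.28-fold lower (31.2 ± 6.58 against 132 ± 15.7 RPKM, adjusted p = 0.00906), the isomerase Idi1 4.87-fold, the cholesterol carrier Stard4 3.99-fold and squalene synthase, Fdft1, 2.77-fold. In the fatty acid synthesis list 4 of 16 tested genes fell and 1 rose (9 and 2 adjusted over the list alone). The desaturase genes Scd and Fads2 were 3.3-fold and 2.18-fold lower, the synthase gene Fasn 2.14-fold and Acss2 2.1-fold lower, and the acyltransferase gene Agpat2 2.63-fold higher. Of 17 glycolytic genes 7 fell and 1 rose (9 and 1 adjusted over the list alone). Lactate dehydrogenase A, Ldha, fell 4.82-fold (47.5 ± 18.6 against 219 ± 27.2, adjusted p = 0.0121), Gpi 3.29-fold, Pgk1 2.65-fold and Eno1 2.51-fold, while the hexokinase Hk2 rose 2.24-fold. Of 37 nuclear genes of oxidative phosphorylation 10 fell and none rose (19 lower adjusted over the list alone). Uqcrh was 2.23-fold lower, Ndufa4 2.16-fold, Ndufa2 2.09-fold and Ndufb5 1.87-fold. Of 13 mitochondrially encoded genes only Mt-nd3 passed, 3.76-fold lower (1 lower adjusted over the list alone). The list of these genes did not pass camera (preset adjusted p = 0.345), though it did without both libraries numbered 2 (preset adjusted p = 0.0436). Of these genes 2 fell without ASA replicate 1 and none without DMSO replicate 1 or 2. Of the Mt-nd3 values 66.7% were not whole reads, so some of its reads were shared with another feature.

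With a preset correlation camera placed the cholesterol (adjusted p = 3.36e-05), fatty acid synthesis (0.0336), glycolysis (0.0018) and oxidative phosphorylation lists (1.52e-07) below other genes. With an estimated correlation none passed (adjusted p = 0.184 for cholesterol and 0.587 for the other 3 lists). Fry, which asks only whether a list moves one way, called cholesterol (adjusted p = 0.00485) and oxidative phosphorylation (adjusted p = 0.0188). Cholesterol genes that fell numbered 15 without ASA replicate 2, 7 without DMSO replicate 2, 3 without DMSO replicate 1 and 0 without ASA replicate 3 or DMSO replicate 3. For glycolysis these counts were 8, 5, 1 and 0, for fatty acid synthesis 6, 0, 0 and 0 (with 2 higher without DMSO replicate 2 and 8 lower without ASA replicate 1), and for oxidative phosphorylation 19, 1, 0 and 0. The fatty acid list lost its preset call without ASA replicate 1 (adjusted p = 0.0524), ASA replicate 3 (0.129) or DMSO replicate 2 (0.209), and with genes shared between lists left out (0.067).

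Some proteasome genes fell and some genes of autophagy and the lysosome rose. All 26 tested proteasome genes had a negative log2 fold change and 8 fell (22 adjusted over the list alone). Psma2 was 2.25-fold lower (86.5 ± 22.3 against 191 ± 10.9 RPKM, adjusted p = 0.0216), Psmb7 1.94-fold, Psmb3 1.85-fold and Psma6 1.82-fold. Of 24 autophagy and lysosome genes 5 rose and 1 fell (11 and 2 adjusted over the list alone). The autophagosome gene Gabarapl1 rose 2.71-fold, the protease gene Ctsb 2.66-fold, Hexa 2.06-fold and Map1lc3a 1.94-fold. Of the Map1lc3a values 25% were not whole reads. Atg16l1, which acts in autophagosome formation, was 2.07-fold lower. The preset camera adjusted p was 4.27e-09 for the proteasome and 0.00154 for autophagy and lysosome, and both had an adjusted p of 0.587 with an estimated correlation. Proteasome calls numbered 15 without ASA replicate 1, 14 without ASA replicate 2, 1 without DMSO replicate 2 and 0 without ASA replicate 3, DMSO replicate 1 or DMSO replicate 3. Autophagy and lysosome genes that rose numbered 7, 8, 2 and 0, and those that fell 1, 2, 1 and 0.

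Among signalling genes, 8 of 22 tested immediate early genes rose and none fell (10 higher adjusted over the list alone). Arc, 16-fold lower, was not in this list. The phosphatase Dusp4 rose 4.41-fold (110 ± 27.6 against 24.2 ± 0.898 RPKM, adjusted p = 0.01), the AP-1 subunits Fosl1 and Fosl2 2.96-fold and 2.1-fold, and Atf3, which belongs to this list too, is given above. Of the Fosl2 values 47.6% were not whole reads. Of 12 TGF-beta targets 5 rose and none fell (7 higher and 1 lower adjusted over the list alone). The inhibitory Smad6 was 4.51-fold higher, Id2 3.39-fold, the matrix protein Fn1 2.98-fold and the ligand Tgfb1 2.94-fold. Of 15 NF-kB targets Icam1 rose 1.56-fold, and Cxcl10 and Sod2 fell 5.08-fold and 2.13-fold (1 higher and 3 lower adjusted over the list alone). Without ASA replicate 2 Cxcl10 was 3.14-fold lower, and 2 of the list rose and 2 fell. Without ASA replicate 1 none rose and 3 fell, and without any 1 of the other 4 libraries none passed. Nfkbia averaged 81 ± 29.1 against 160 ± 43.7 (adjusted p = 0.0736). Among 6 tested Wnt/beta-catenin targets and components only Ctnnb1, beta-catenin itself, passed, 1.59-fold lower (2 higher and 1 lower adjusted over the list alone). Cd44 and Myc had log2 fold changes of 0.67 and 0.34 (adjusted p = 0.0639 and 0.257). In this list 1 rose and 1 fell without ASA replicate 1, 2 and 1 without ASA replicate 2, and none without any 1 of the other 4 libraries. The immediate early (adjusted p = 2.88e-05) and TGF-beta lists (0.00112) passed camera with a preset correlation but not with an estimated correlation (adjusted p = 0.184 and 0.587). Fry called the immediate early list as well (adjusted p = 0.00485). The NF-kB (preset adjusted p = 0.917) and Wnt lists (0.614) passed none of the 3 tests. Immediate early genes that rose numbered 11 without ASA replicate 2, 3 without DMSO replicate 2, 1 without DMSO replicate 1 and 0 without ASA replicate 3 or DMSO replicate 3. For TGF-beta targets these counts were 8, 1, 3 and 0. Over the 6 fits that each left out a library, Nfkbia passed without ASA replicate 1 (adjusted p between 0.0319 and 0.226) and Cd44 without ASA replicate 1 or 2 (adjusted p between 0.0362 and 0.246).

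**Figure D4:**
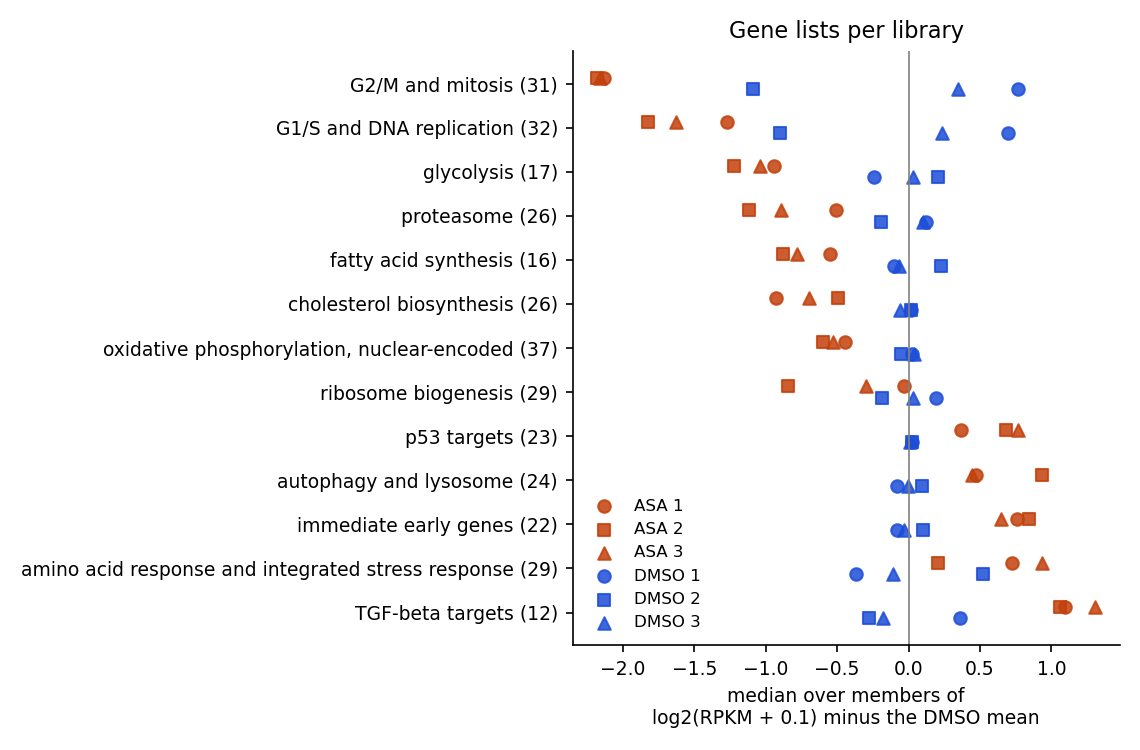
For each of the 13 gene lists past the preset camera test, the median over its tested members (their number in parentheses) of log2(RPKM + 0.1) minus the DMSO mean, with 1 point per library, ASA in orange and DMSO in blue. For G2/M and mitosis the ASA libraries lie at -2.18 to -2.13 and DMSO replicate 2 at -1.09.

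The target of aspirin itself was measured. Ptgs1, which encodes cyclooxygenase 1, averaged 72.6 ± 16.2 RPKM in ASA and 34.2 ± 6.01 in DMSO libraries (SD, n = 3), 2.11-fold higher (log2 fold change 1.07 ± 0.23 SE, adjusted p = 0.0336). It spans 15560887 to 15581417 of chromosome 3 (Rnor_6.0). Ptgs2, cyclooxygenase 2, had no row in the table. The prostaglandin D synthase Ptgds rose 2.64-fold (25 ± 4.28 against 9.32 ± 0.566, adjusted p = 0.0178). These were the only genes past the threshold of 13 tested in the prostaglandin and eicosanoid list, over all genes and adjusted over the list alone. The list as a group did not pass (preset camera adjusted p = 0.345). In it 2 rose and 1 fell without ASA replicate 1, 3 and 0 without ASA replicate 2, 1 and 0 without DMSO replicate 2, and none without any 1 of the other 3 libraries. Ptgs1 lost its call without DMSO replicate 1, 2 or 3 or ASA replicate 3, with an adjusted p between 0.0299 and 0.165 and a fold between 1.9 and 2.39 over the 6 fits that each left out a library.

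Of the enzymes that write and remove DNA methylation, Tet2 averaged 12.6 ± 2.2 RPKM in ASA and 11.9 ± 1.43 in DMSO libraries and Tet3 4.32 ± 1.67 and 4.99 ± 0.541 (adjusted p = 0.863 and 0.631). Tet1 (0.887 ± 0.383 against 2.52 ± 0.225) and the maintenance methyltransferase Dnmt1 (31.1 ± 5.15 against 80 ± 34.9) had log2 fold changes of -1.48 ± 0.40 and -1.26 ± 0.35 (SE) that missed the threshold (adjusted p = 0.0538 and 0.058). Dnmt1 passed without DMSO replicate 2, whose value was 42.8 against 112 and 85.4 in DMSO replicates 1 and 3 (adjusted p = 0.024, and 0.024 to 0.212 over the 6 fits). Tet1 passed without ASA replicate 1 (adjusted p = 0.0368) or ASA replicate 2 (adjusted p = 0.0342, and 0.0342 to 0.222 over the 6 fits). In the list of 20 DNA methylation and demethylation genes, Gadd45a rose and Idh2 fell 1.61-fold over all genes. Adjusted over the list alone 2 were higher and 3 lower, with Tet1 and Dnmt1 among the lower ones, and the list did not pass camera (preset adjusted p = 0.885). Over all genes 2 rose and 3 fell without ASA replicate 1, 4 and 3 without ASA replicate 2, 1 and 2 without DMSO replicate 2, and none without any 1 of the other 3 libraries.

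Pituitary genes changed in part. Cga, the alpha subunit shared by the glycoprotein hormones, fell from 25.8 ± 2.33 to 2.86 ± 1.54 RPKM (SD, n = 3), 9.84-fold (log2 fold change -3.30 ± 0.45 SE, adjusted p = 0.0137). It spans 50390591 to 50391845 of chromosome 5 (Rnor_6.0). Prl had a log2 fold change of -0.44 ± 0.71 (SE) and Pomc of -0.50 ± 0.47 (adjusted p = 0.7 and 0.492). The Prl values of either group differed by more than the group means did. Of 9 tested pituitary transcription factors 2 fell (2 lower adjusted over the list alone), among them the neurogenic factor gene Neurod4, 2.94-fold. Egr1 had a log2 fold change of 1.27 (adjusted p = 0.131). Of 9 tested pituitary receptors the estrogen receptor Esr1 fell 2.55-fold (41.9 ± 7.48 against 107 ± 22.3, adjusted p = 0.0189), and 4 were lower adjusted over the list alone. The dopamine receptor gene Drd2, the somatostatin receptor gene Sstr2 and Thrb had log2 fold changes of -1.15, -2.00 and -1.88 (adjusted p = 0.0587, 0.0503 and 0.0705). Among 20 secretory granule and neuroendocrine genes 2 rose and 3 fell (5 and 4 adjusted over the list alone). Syt4 and Vamp2 were 2.16-fold and 1.58-fold higher, and Syt1, the convertase gene Pcsk2 and Syp 2.51-fold, 2.35-fold and 1.82-fold lower. Drd2, Sstr2 and Thrb passed without ASA replicate 2 (adjusted p = 0.0109, 0.0248 and 0.017), with Thrb 2.22-fold lower against 3.68-fold with all libraries. Sstr2 and Thrb also passed without ASA replicate 1, and Egr1 passed without ASA replicate 2 (adjusted p = 0.0368). Over the 6 fits that each left out a library, the adjusted p of these 4 genes reached 0.183, 0.177, 0.224 and 0.373. Receptor genes that fell numbered 3 without ASA replicate 1 and 4 without ASA replicate 2, and none did without DMSO replicate 1. Transcription factor genes that fell numbered 3 without ASA replicate 1 and 1 without DMSO replicate 1 or 2, and 1 rose without ASA replicate 2. Of the granule genes 1 rose and 3 fell without ASA replicate 1, 5 and 3 without ASA replicate 2, 1 and 0 without DMSO replicate 2, and none without DMSO replicate 1. The transcription factor, receptor and granule lists did not pass camera (preset adjusted p = 0.408, 0.32 and 0.885). Cga passed without ASA replicate 1 or 2 or DMSO replicate 2 and not without ASA replicate 3, DMSO replicate 1 or DMSO replicate 3 (adjusted p between 0.00711 and 0.0866, 6.83-fold to 12.6-fold lower).

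Some markers of other cell types changed, in both directions. Of 9 tested fibroblast and mesenchymal genes the proteoglycan Dcn and the receptor Pdgfrb rose 2.49-fold and 3.89-fold and Tagln fell 4.5-fold (2 and 2 adjusted over the list alone), with Col5a1 at a log2 fold change of -1.09 (adjusted p = 0.0624). Of 5 leukocyte markers Cd68 rose and Cd3e fell 2.8-fold (1 and 1 adjusted over the list alone), while Cd14 and Fcer1g had log2 fold changes of -1.41 and 0.58 (adjusted p = 0.165 and 0.282). Cd14 had a log2 fold change of -0.73 without ASA replicate 2. Anxa1, 1 of 5 tested folliculostellate and glial markers, fell 3.18-fold (528 ± 139 against 1705 ± 514 RPKM, adjusted p = 0.0228), with 1 higher and 1 lower adjusted over the list alone. Cryab, Cldn9 and Slc1a3 did not pass (adjusted p = 0.0741, 0.533 and 0.551). Of 8 epithelial and stem cell markers Krt19 fell 8.19-fold and Cldn4 rose 5.36-fold (2 lower and 1 higher adjusted over the list alone). Krt19 was 14.3-fold lower without DMSO replicate 1 and 5.18-fold without DMSO replicate 2, and Cldn4 8.25-fold higher without ASA replicate 1. Krt8 and Krt18 had log2 fold changes of -0.89 and -0.75 (adjusted p = 0.0594 and 0.212). The endothelial genes Eng and Vwf stayed at 1.13 RPKM or less in all 6 libraries, with adjusted p of 0.698 and 0.706. Without ASA replicate 1 Col5a1, Cd14, Cryab and Krt8 passed, and Krt8 did so without ASA replicate 2 too. Their adjusted p lay between 0.0403 and 0.181, 0.0488 and 0.42, 0.0398 and 0.194, and 0.0298 and 0.228 over the 6 fits that each left out a library. Without DMSO replicate 1 only 1 of the calls in these lists was left, an epithelial marker that fell, and without DMSO replicate 2 1 leukocyte marker rose and 1 folliculostellate marker fell. None of the 4 of these lists with enough members passed camera (preset adjusted p = 0.885 for fibroblast, 0.912 for leukocyte, 0.885 for folliculostellate and 0.614 for epithelial markers).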

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

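Library quality weights, voom, the median exon, leaving out both libraries numbered 2, and totals without mitochondrial and Prl reads were chosen after seeing the data. All 4 counts (genes changed, higher, lower and lists changed) stayed within 1.5 times under other pseudocounts, filters, scalings and variance models, with 1043 to 1892 genes changed, 618 to 1037 higher, 425 to 855 lower, and 13 or 14 lists changed. With a log2 fold change minimum of 1, 1102 genes changed, 593 higher and 509 lower. Leaving out each library in turn moved them to between 0 and 2617 genes changed, 0 and 1608 higher, 0 and 1034 lower, and 12 and 13 lists. The libraries behind counts outside 1.5 times were ASA replicates 2 (2617 changed) and 3 (0), DMSO replicates 1 (91), 2 (632) and 3 (0), and for the lower genes also ASA replicate 1 (1034). Each of these fits left out a single library and had the same residual degrees of freedom, so these do not account for the differences between the fits. The fits with 0 genes kept the pair of replicates with the lowest correlation of log2 RPKM in its group. This was 0.918 for ASA replicates 1 and 2, against 0.944 and 0.977 for the other ASA pairs. It was 0.969 for DMSO replicates 1 and 2, against 0.983 and 0.989. The cause was not tested further. Library quality weights gave 5745 genes changed (3168 higher, 2577 lower), leaving out both libraries numbered 2 gave 3153 (1734 and 1419), and the median exon per gene gave 900 (496 and 404). The quality weight was 8.71 for DMSO replicate 3 and 0.105 for ASA replicate 2, against 0.536 to 1.91 for the other libraries. The weighted count thus rests largely on DMSO replicate 3 in its group and little on ASA replicate 2. The cause of these counts was not tested. Voom on the recovered reads gave 1382 genes, 1278 of them among the 1400, and totals without mitochondrial and Prl reads gave 1532. With an estimated correlation camera called 0 lists (smallest unadjusted p = 0.00705), and fry called 3.

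Of 188 named genes or genes the rule could name, 128 passed the threshold, and 98 of these kept direction and call under the 9 alternatives of pseudocount, filter, scaling and variance model. Most calls lost there were lost by eBayes without a trend (29) and equal RPKM sums (20). None of the 128 kept its call without every single library in turn, since no gene passed without ASA replicate 3 or DMSO replicate 3. Of the 60 that did not pass, 23 passed without ASA replicate 1, 21 without ASA replicate 2 and 1 without DMSO replicate 2. Changes of sign were seen only for genes that passed in neither fit, and their cause was not tested. Leaving out each library in turn gave log2 fold changes of -0.0059 (without ASA replicate 3) to 0.225 for Tet2, -0.533 to 0.055 (without ASA replicate 2) for Tet3, and -1.01 to 0.065 (without ASA replicate 1) for Prl. The values were -0.532 to 0.072 (without ASA replicate 2) for Eng, -0.102 (without DMSO replicate 3) to 0.513 for Vwf, and -0.072 (without DMSO replicate 2) to 0.594 for Slc1a3. Without ASA replicate 2 Tet2 was also below 0. Library quality weights gave Tet3 0.026 and Eng 0.239, leaving out both libraries numbered 2 gave 0.135 and 0.261, and the median exon gave Tet2 -0.104, Vwf -0.015 and Akr1b1 -0.056. No paired analysis was made, because the labels give no replicate numbers shared between the groups. Count models were planned only for deposited whole-number counts and were not run. At this number of libraries the simulated test recovered 10.4% of genes changed 2-fold, with at least 66492445 reads per library. Only 200 genes were changed in it, so that rate may not hold for the real data.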

Other observations

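The tests of coverage in ASA replicate 2 and DMSO replicate 2, of the position of DMSO replicate 2 between the groups, of the leukocyte markers and of the number of genes over other splits were chosen after the result was seen. Some polyamine genes and NRF2 targets changed, in both directions. Sat1, which encodes the enzyme that acetylates polyamines for breakdown, rose from 120 ± 4.99 to 757 ± 337 RPKM (SD, n = 3), 5.79-fold (adjusted p = 0.0143). Odc1, the first enzyme of polyamine synthesis, rose 1.93-fold, and Oaz1, the antizyme that marks it for degradation, fell 1.82-fold. These were 3 of 8 tested polyamine genes (2 higher and 2 lower adjusted over the list alone). Of the Sat1, Odc1 and Oaz1 values 38.9%, 26.7% and 44.4% were not whole reads. Of 23 tested NRF2 targets Osgin1, Gstp1, Abcc1 and Nfe2l2 rose 2.41-fold, 2.31-fold, 2.2-fold and 1.78-fold and the peroxiredoxin Prdx1 fell 2-fold (7 higher and 2 lower adjusted over the list alone). In the list of fatty acid oxidation and PPAR targets, 3 of 23 rose and 2 fell (6 and 6 adjusted over the list alone). Acot2 was 5.75-fold higher, the lipid droplet gene Plin2 2.33-fold and the muscle carnitine transferase Cpt1b 2.06-fold, while the liver form Cpt1a and the uncoupling protein Ucp2 were 2.45-fold and 2.33-fold lower. Of 17 hypoxia response genes Ankrd37 fell 6.89-fold and Higd1a 2.1-fold (4 lower adjusted over the list alone), and Pdk1 and Bnip3l had log2 fold changes of -1.12 and -0.69 (adjusted p = 0.0507 and 0.0562). None of these 4 lists passed camera with a preset correlation (adjusted p = 0.885, 0.206, 0.917 and 0.382), though the hypoxia list did without DMSO replicate 1 (adjusted p = 0.0254, and 0.0254 to 0.896 over the 6 fits that each left out a library). Each of these calls was lost without ASA replicate 3 or DMSO replicate 3, and without DMSO replicate 1 only Acot2 and Ankrd37 passed. Without ASA replicate 2, 9 NRF2 targets rose and 1 fell, 6 genes of fatty acid oxidation rose and 5 fell, 1 hypoxia gene rose and 3 fell, among them Bnip3l, and 2 polyamine genes rose and 2 fell. Without DMSO replicate 2 the counts were 1 and 1, 3 and 0, 0 and 1, and 1 and 0. Without ASA replicate 1 they were 5 and 2, 3 and 5, 1 and 2, and 1 and 2.

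Few genes of the other lists passed. Among 29 ribosome biogenesis genes Nop56 and Fbl fell 2.21-fold and 2.1-fold (0 adjusted over the list alone), and the list passed camera with a preset correlation (adjusted p = 0.0146) but not with an estimated correlation (adjusted p = 0.896). It did not pass without ASA replicate 2 (adjusted p = 0.0598) or DMSO replicate 1 (adjusted p = 0.0727). None of 38 cytosolic ribosomal protein genes passed, and the list did so only without ASA replicate 1 (adjusted p = 0.000878, against 0.404 with all libraries). Rpl12, Rps12, Rplp1 and Rplp0 had log2 fold changes of 2.02, 0.99, 1.09 and 0.51 (adjusted p = 0.0903 to 0.253), with Rpl12 at 639 RPKM in ASA replicate 2 against 42.7 to 148 in the other 5 libraries. With 1 library left out in turn, Rpl12 was 2.24-fold to 6.43-fold and Rplp1 1.4-fold to 2.86-fold higher, both least without ASA replicate 2. Of 18 heat shock genes Hsf1 rose 1.9-fold (1 higher and 2 lower adjusted over the list alone), and Stip1 and Dnaja1 had log2 fold changes of -1.18 and -1.17 (adjusted p = 0.0551 and 0.059). Of the Hsf1 values 30.8% were not whole reads. Of 27 interferon-stimulated genes the peptide transporter gene Tap1 rose 1.66-fold (0 adjusted over the list alone), while Rsad2, Isg20 and B2m had adjusted p of 0.0546, 0.0808 and 0.116. Of 20 AMPK and mTORC1 components Eif4ebp1 and Sesn2 rose 2.48-fold and 2.55-fold (3 higher and 1 lower adjusted over the list alone). Of 15 glutathione and cysteine genes only Gstp1 passed over all genes (2 higher adjusted over the list alone), and none of 6 xenobiotic genes or 2 histone genes did. Without ASA replicate 1 or 2 Rpl12, Stip1 and Dnaja1 passed, without ASA replicate 1 Rps12 and without ASA replicate 2 Rsad2. Over the 6 fits that each left out a library, the lowest adjusted p of these 5 genes was 0.0305, 0.026, 0.026, 0.032 and 0.0295, and the highest 0.243, 0.203, 0.202, 0.383 and 0.189. Without ASA replicate 1, 2 heat shock genes rose and 4 fell, and 1 AMPK and mTORC1 component rose and 2 fell. Without ASA replicate 2 these counts were 1 and 2, and 3 and 2, and 3 interferon-stimulated genes rose. Of the xenobiotic genes 1 rose without ASA replicate 1 and without ASA replicate 2, and 1 histone gene fell without ASA replicate 2. Of the glutathione genes 2 rose and 1 fell without ASA replicate 1, and 2 rose without ASA replicate 2. Ribosome biogenesis genes that fell numbered 4 without ASA replicate 1, 3 without ASA replicate 2 and 1 without DMSO replicate 2. Of the remaining lists only 1 AMPK and mTORC1 component passed without DMSO replicate 2, higher, and none of the genes of these lists passed without DMSO replicate 1. None of these lists other than ribosome biogenesis passed camera with a preset correlation and all libraries. The median and the mean log2 fold change of a list differed in sign for NF-kB (0.04 and -0.16) and granule genes (0.01 and -0.06). They did so too for fatty acid oxidation (-0.26 and 0.06), polyamine (-0.22 and 0.08), glutathione (-0.04 and 0.24), fibroblast (-0.12 and 0.02) and leukocyte genes (-0.45 and 0.42), and for heat shock genes (-0.13 and 0.004). None of these 8 lists passed camera.

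ASA replicate 2 lay apart from the other 5 libraries. Lower depth is argued against: thinned to its depth, the other ASA libraries reached at most 0.69 of its distance from the DMSO mean. For a larger response along the same genes, the other ASA libraries accounted for 0.41 of the variance of its difference from DMSO, under the 0.5 set for that test. Its uneven coverage lowers that share whatever the size of its response, so the share cannot decide. The slope of its difference on theirs was 1.03. Over the 2617 genes called without it the median ratio was 0.98, so no larger response was seen along those genes, which were chosen by their change in the other ASA libraries. Uneven coverage of transcripts, with a scatter of exons 4.16 times the highest of the other libraries, is a candidate explanation that stays open, as does RNA quality, for which there is no label. Its median log2 ratio of reads in the first to the last 20% of a gene's exons was -0.4, against -0.28 to -0.23 elsewhere. Exons of at least 1000 bases minus those under 150 bases differed from DMSO by -0.32 (log2), against -0.04 to 0.08 elsewhere.

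DMSO replicate 2 had lower cell cycle genes than the other DMSO libraries. A share of RNA or cells from the ASA group would move all called genes by the same part of the way to the ASA level. Against this, among the 3153 genes called without both libraries numbered 2, 30 G2/M genes had gone a median of 0.82 of the way and 3091 genes outside the cell cycle lists 0.19, a difference of 0.63, and the quartiles (0.79 to 0.86 and -0.01 to 0.51) did not overlap. Its exon scatter was 1.04 times the highest of the other DMSO libraries, which argues against uneven coverage. A lower share of dividing cells in that culture may be behind it, as an untested hypothesis, and the labels give neither density nor passage.

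Cd68 was higher in all 3 ASA libraries, at 28.9, 210 and 69.4 RPKM against 1.9 to 3 in DMSO. The other tested leukocyte markers, Cd74, Cd14, Cd3e and Fcer1g, had a median log2 difference of -0.93 and a highest of 0.58. This argues against a rise of leukocyte transcripts that these markers share with Cd68. Cd74, an abundant leukocyte transcript, had 9.67 to 23.6 RPKM in ASA and 14.2 to 27.3 in DMSO libraries. Itgax, a leukocyte gene outside that list, rose 18.1-fold, and markers seen in only 1 of the groups could not be listed in the table. The test thus rests on 4 markers, of which Cd3e marks T cells and not macrophages. It cannot decide about a leukocyte type that carries Cd68 and Itgax. Uneven coverage of ASA replicate 2 is argued against by a log2 difference of 4.14 without it. A response of the cells' own lysosomal genes may be considered as a hypothesis and was not tested. In the combined list of autophagy and lysosome genes 5 of 24 rose and 1 fell, with the autophagy genes Gabarapl1 and Map1lc3a among those that rose.

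Other splits of the 6 libraries into 3 and 3 number only 10, the real one included, too few for a share under 0.05. The real split gave 1400 genes and the other 9 splits at most 0 genes by limma, with up to 858 genes at an unadjusted p under 0.05 against 3753, so 1 of the 10 splits, the real one, gave that many genes. For gene lists at the preset correlation the real split called 13 and the others between 2 and 12, so again 1 of the 10, the real one, gave that many. Each of the other 9 splits put ASA libraries on both sides. Part of any ASA difference then stays between the sides, where it can raise list calls. The rest adds to the spread within the sides, which lowers gene calls. The counts in those splits are therefore not a background without an ASA effect and cannot decide. The preset test called nearly as many lists in some of them. A preset call alone does not tell an effect of ASA from other differences between the libraries. No overlap between the 3 ASA and 3 DMSO values was seen for 4840 of 12502 genes, 38.7%, where the mean over all 10 splits is 10%. The share in each of the other 9 splits was not computed. Genes vary together, so a single split can lie far from that mean, and the difference does not decide about chance.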
